A study of Homo sapiens with 3 samples.

How the data were processed

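Total RNA from GFP-SAS cells, a human tongue carcinoma line, was labelled from 10 ng with a 3' in vitro transcription kit and hybridised to Affymetrix arrays, per the labels. There were 3 libraries, 1 with the non-targeting siRNA siNT and 2 with siRNAs against AKT1 (numbers 22 and 58), each at 10 nM for 24 h. The deposited values are log2 expression values per probe set, and RMA is named in the submitters' processing notes without version or settings. The software, the scan dates and any hybridisation batches are not given in the sources used here. That the scale is log2 was read from the values, which ran from 2.20 to 13.4 with near-equal medians, and the sorted columns differed by at most 0.181. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a set by median polish. With 3 arrays that summary often gives exactly equal values: 45.3% of probe sets were tied between some pair of libraries and 20.7% across all 3. Values near the floor understate differences, and no detection calls were used here.

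Of 49386 probe sets, 93 were control probe sets, 45253 carried 1 gene symbol in the platform annotation, 1327 carried several and 2713 were not listed. Symbols were updated through Entrez identifiers where the reference table allowed (45172 probe sets; 81 kept the older symbol). Probe sets with several genes, unlisted ones and controls were left out of the gene tests; 6 of the controls name a gene. The probe set with the highest mean log2 value stood for its gene, giving 18239 genes, and the 12779 with a mean at or above the 30th percentile (log2 3.93) were tested. Where a gene's probe sets differ, this choice favours the brightest.

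Both siAkt1 libraries formed one group, as their labels give them the same genotype. Genes were counted where the log2 difference from siNT was at least 1 in each siAkt1 library. The group was also compared with siNT by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, threshold 0.05), with 1 residual degree of freedom and an estimated prior of 0.467 degrees of freedom. The single siNT library is thereby assumed to vary like the siAkt1 libraries. For 27 gene lists the median difference per siRNA was computed, and for the 25 with at least 5 measured members it was placed among 10000 random lists of the same size matched on mean log2 value, and a list was called higher or lower where it lay beyond the 2.5th or 97.5th percentile with both siRNAs. The same 25 lists were tested with camera at a preset correlation of 0.01 and at an estimated one, Benjamini-Hochberg over the lists.

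The genes named in the text were drawn by a rule: AKT1 and AKT2; the 12 highest and 12 lowest genes by the smaller of the differences with the siRNAs; up to 4 leading members of each list and up to 2 on its other side; and the 5 genes at each end of the difference between the siRNAs. MYC, ACTB, GAPDH and the genes marked in the scatter plot outside this rule, CCND2 among them, were chosen after their values were seen, as were the members of the interferon, RNA interference and actin genes named in the closing paragraphs. Grouping, tests, gene lists, the naming rule and the alternatives (averaged probe sets, median centring, quantile normalization, no or a stricter filter, 1.5-fold, other eBayes settings, an estimated correlation, probe sets as the unit, each siAkt1 library left out) were fixed before the data were examined. A loess correction on mean log2 value, the removal of tied genes and 3 further gene lists were added after seeing the data.

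The steps were tested on simulated data: 3 libraries for the 12779 genes with noise resampled from the difference between the siRNAs within 50 intensity bins, and 200 genes changed. The size rule found 38% of genes at a log2 difference of 1, 91.5% at 2 and 99.5% at 3, and also called 470, 483 and 485 unchanged genes. Limma found 0 of 200 at each size. Of 25 lists shifted by 0.5, all 25 lay beyond the percentiles and 25 passed camera. Among lists left unshifted there, 1 lay beyond the percentiles and 0 passed camera. With a shift of 1, camera passed 1 unshifted list. Noise was drawn gene by gene, so members of simulated lists were uncorrelated, whereas the measured G1/S genes had an estimated correlation of 0.693. False calls of correlated lists were therefore not tested. The simulated noise includes whatever differs between the siRNAs, so it overstates pure measurement noise by an unknown amount. Unchanged libraries that share 1 control were drawn 100 times in the same way.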

Results

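Gene expression was measured on 3 Affymetrix arrays in GFP-SAS cells, the labels' name for a culture of SAS, an established human tongue carcinoma line. The cells had been exposed for 24 h to 10 nM of a small interfering RNA (siRNA), a short duplex that directs cleavage of matching mRNA. A non-targeting siRNA (siNT) served as the control in 1 library, and a pair of siRNAs against AKT1, siAkt1-22 and siAkt1-58, was used in 1 library each. The question was how the expression profile of these cells differed after knockdown of AKT1. The deposited log2 values had medians of 4.59 with siNT, 4.59 with siAkt1-22 and 4.58 with siAkt1-58 over 49386 probe sets, and the number of arrays limits the precision of every value. All values are log2 differences from siNT unless stated. The labels do not say that the libraries came from separate cultures, so limma's p-values measure only the spread between these samples. With 1 siNT library, that spread and every SD come from siAkt1-22 against siAkt1-58 and hold sequence-specific effects. Camera with its preset correlation compares the genes of a list with other genes, so its p-values do not measure spread between samples.

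AKT1, the serine/threonine kinase of the PI3K pathway that both siRNAs target, read 8.46-fold lower with siAkt1-22 and 9.71-fold lower with siAkt1-58 than with siNT. Its log2 value was 6.75 with siNT, 3.67 with siAkt1-22 and 3.47 with siAkt1-58, a mean difference of -3.18 ± 0.14 (SD, n = 2). Both knockdown values lay below the filter level of 3.93, where dim signal limits the fold that can be read, so these folds do not measure the remaining mRNA. Ranked by the smaller of the differences with the siRNAs, AKT1 was number 1 of the 12779 genes tested. Another AKT1 probe set was lower by -1.23 and -1.29, and the last one read 3.47 in all 3 libraries. Averaging the probe sets gave a difference of -1.48. AKT2, a related kinase, was -0.97 with siAkt1-22 and -0.02 with siAkt1-58, and a dimmer AKT2 probe set (5.45 with siNT) was -2.01 with siAkt1-22 and -0.01 with siAkt1-58.

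Beyond the target, TGFBR1, the type I receptor for TGF-beta, was lower by -3.87 with siAkt1-22 and -2.77 with siAkt1-58. Its other probe sets were dim, at 2.77 and 3.39 with siNT, and showed differences from -0.28 to 0. IGFBP3, a carrier of insulin-like growth factors, was lower by -2.23 and -2.29, and CCN2, a matricellular growth factor, by -2.05 and -3.09. The receptors LIFR (-2.73 and -1.85) and IL7R (-2.46 and -1.75), the zinc finger factor PLAGL1 (-2.19 and -2.11) and the replication helicase DNA2 (-1.93 and -2.36) were also lower with both siRNAs. So were ZNF367 (-1.98 and -3.44), MYEOV (-2.14 and -1.91), KLHL15 (-1.81 and -2.23) and SGMS2, a sphingomyelin synthase (-1.74 and -2.15). A dimmer LIFR probe set was -1.91 and -0.48.

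On the other side, CDKN2B, which encodes the CDK4/6 inhibitor p15, was 5.47-fold higher with siAkt1-22 and 8.44-fold higher with siAkt1-58. The tetraspanin TSPAN31 was 5.66-fold and 5.17-fold higher, and TXNIP, a thioredoxin-binding protein that restrains glucose uptake, higher by 2.18 and 1.87 with all 5 of its probe sets on the same side. Higher values were also found for the adhesion molecule NECTIN4 (2.13 and 1.62), the mitochondrial pyrophosphatase PPA2 (2.01 and 1.98) and the myosin light chain MYL12B (1.75 and 2.04). Other leading genes were CHIC1 (2.06 and 2.39), ANKRD22 (1.69 and 2.61) and ST6GALNAC2 (1.71 and 2.05). VAV3 (1.59 and 1.66), RITA1 (1.79 and 1.58) and EHD2 (1.60 and 1.58) followed. Other probe sets above the filter level showed smaller differences for EHD2 (0.28 and 0.35), NECTIN4 (0.89 and 0.30) and CHIC1 (0.04 and 0). The same held for VAV3 (0.01 and 0.21). A dimmer ANKRD22 probe set (3.82 with siNT) was 0.58 and 2.13. Other PPA2 probe sets above the filter level were split. Differences of 2.13 and 2.21, and of 1.77 and 1.61, stood beside -0.01 and 0.06, and 0 and 0.

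In all, 94 genes were at least 2-fold higher and 150 at least 2-fold lower than siNT with both siRNAs, by a rule of size without a test. Single siRNAs gave more: 562 higher and 763 lower with siAkt1-22, and 197 higher and 457 lower with siAkt1-58. Both differences rest on the same siNT library, which cannot be split. Libraries simulated without any effect, with noise drawn from the difference between the siRNAs, gave means of 247 higher genes (204 to 282 over 100 draws) and 244 lower genes (200 to 296), more than were observed; that noise holds whatever differs between the siRNAs. Independent lists of the same lengths would share 8.66 higher and 27.3 lower genes. Averaging the probe sets of a gene gave 43 genes at least 2-fold higher than siNT in both siAkt1 libraries and 99 genes at least 2-fold lower than siNT in both siAkt1 libraries; a limit of 1.5-fold in place of 2-fold gave 409 and 458.

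No gene passed limma's moderated test of both siAkt1 libraries against siNT (0 higher and 0 lower, lowest adjusted p = 0.607), and 954 genes had an unadjusted p under 0.05. In simulated libraries of this design limma found 0 of 200 genes changed by a log2 difference of 3, so the count of 0 does not show that genes kept their level. Across genes, which are not independent replicates, the differences with the siRNAs correlated with Pearson's r of 0.385, against 0.499 in the simulated unchanged libraries, and the covariance was 0.115 against 0.195, a difference of -0.080. The simulated noise holds the differences of siAkt1-22 from siAkt1-58, so these values do not separate noise in siNT from an effect shared by the siRNAs.

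**Figure D1:**
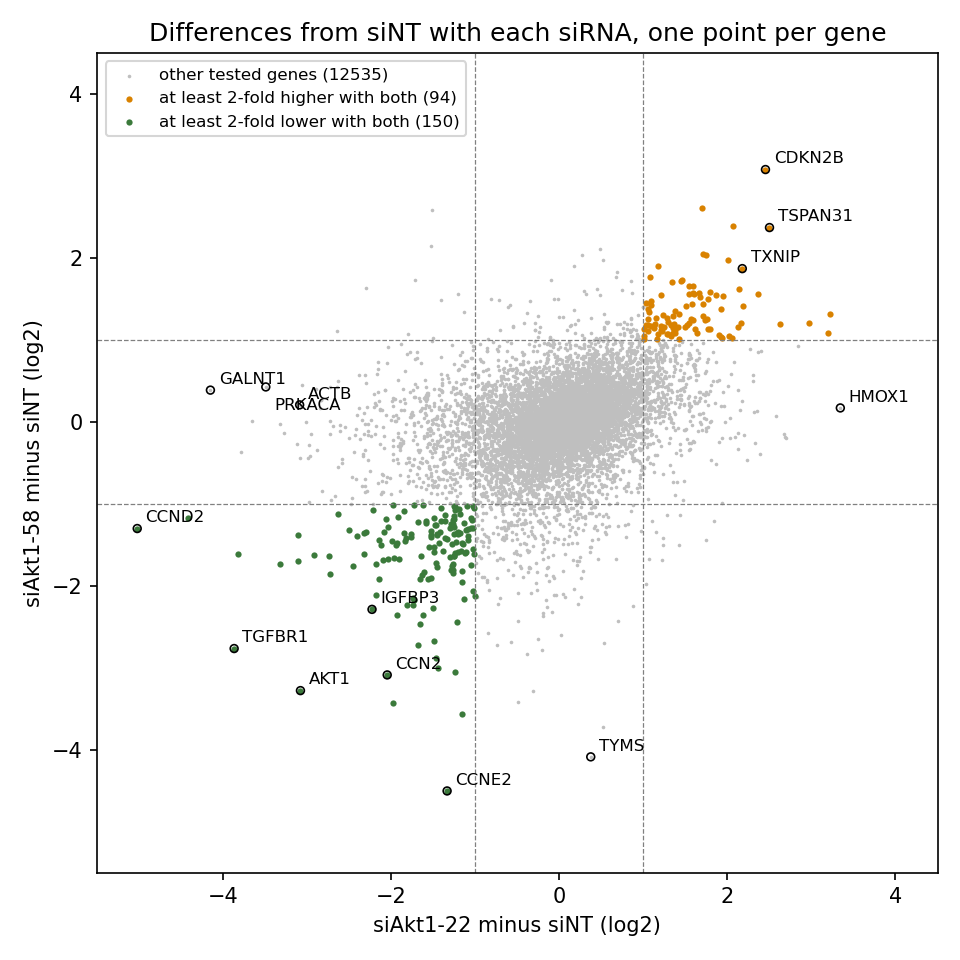
Each point is 1 of the 12779 tested genes, with its log2 difference from siNT for siAkt1-22 on the horizontal axis and for siAkt1-58 on the vertical axis; dashed lines mark 2-fold. The 94 genes at least 2-fold higher with both siRNAs are orange, the 150 at least 2-fold lower are green, and AKT1 lies at -3.08 and -3.28.

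Cell cycle genes had medians below siNT with both siRNAs. Of 25 measured G1/S genes, 19 were below siNT with both siRNAs and 6 of them at least 2-fold; the list's median was -0.28 with siAkt1-22 and -1.47 with siAkt1-58. The replicative helicase subunit MCM6 was -2.18 and -1.74, the ubiquitin ligase adaptor DTL -1.47 and -1.72, the cyclin CCNE2 -1.34 and -4.50, and the flap endonuclease FEN1 -1.23 and -1.47. With siAkt1-58, 16 of the 25 genes were at least 2-fold lower, against 6 with siAkt1-22. Of 28 measured G2/M genes, 25 were lower with both siRNAs, with medians of -0.43 and -0.77. The mitotic kinesin KIF11 was -1.19 and -0.79, the proliferation marker MKI67 -2.28 and -0.85, and the spindle factor TPX2 -0.85 and -0.76.

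**Figure D2:**
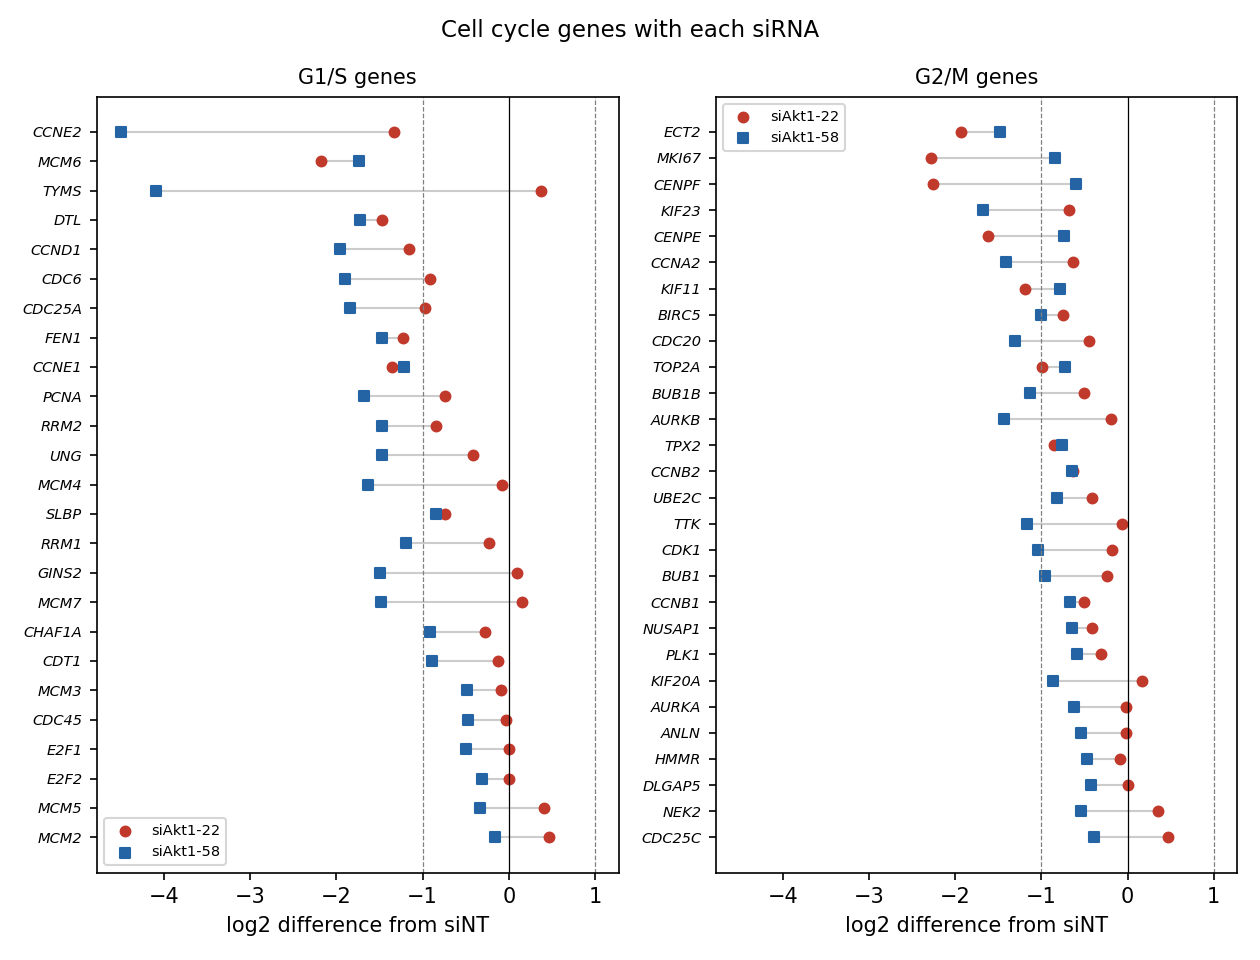
Log2 difference from siNT (horizontal axis) of each measured G1/S gene (left) and G2/M gene (right), with siAkt1-22 as red circles and siAkt1-58 as blue squares; dashed lines mark 2-fold. The siAkt1-58 values lie below 0 for all 25 G1/S genes, and CCNE2 reaches -4.50.

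MYC and ribosome biogenesis genes were lower as well, with 16 of 21 measured members below siNT with both siRNAs and medians of -0.41 and -0.47. The polyamine enzyme ODC1 was -2.63 and -1.13, the pseudouridine synthase DKC1 -0.83 and -0.73, UTP20 -0.74 and -0.80, and NOP2 -0.98 and -0.62. MYC itself was -0.41 and 0.18. These 3 lists passed limma's camera with its preset correlation (adjusted p = 4.01e-06 for G1/S genes, adjusted p = 3.34e-07 for G2/M genes and adjusted p = 6.75e-07 for MYC and ribosome biogenesis genes). None passed with an estimated correlation, and no member passed limma adjusted over the list alone. Both rest on 1 residual degree of freedom and could hardly pass anything, so these failures do not show that the lists kept their level. The preset correlation of 0.01 treats genes as nearly independent, and the small p-values rest on that assumption. Estimated correlations were 0.693 for G1/S genes, 0.222 for G2/M genes and -0.048 for MYC and ribosome biogenesis genes. These estimates also come from 1 residual degree of freedom. Camera passed 6 lists with averaged probe sets and 6 with median-centred arrays. The medians lay at or below the 0.6th percentile of 10000 random lists matched on expression with either siRNA.

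Matrix and invasion genes had medians of -0.40 and -0.34, below the 0.1th percentile with both siRNAs. CCN1, a relative of CCN2, was -0.41 and -1.07, the urokinase PLAU -0.42 and -0.67 and thrombospondin THBS1 -1.24 and -0.48. The protease inhibitor TIMP3 was 0.55 and 0.42 in its brightest probe set, but 0.24 and -0.02, and 0.01 and -0.37, in others nearly as bright. Autophagy and lysosome genes were higher, with medians of 0.39 and 0.20 and 13 of 20 members above siNT with both siRNAs. The autophagy kinase ULK1 was 1.01 and 0.73, BECN1 1.05 and 0.48, and the lysosomal enzymes HEXA 0.74 and 0.47 and NEU1 1.33 and 0.47. Neither list passed camera (adjusted p = 0.180 for matrix genes and adjusted p = 0.0630 for autophagy genes). With a stricter filter on dim genes the medians no longer lay beyond the chosen percentiles in both siRNAs for either list, and with averaged probe sets the matrix list lost that place too. The number of lists called higher was 1 as reported, 3 without a filter, 0 with the stricter filter and 4 with probe sets as the unit.

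Epithelial junction genes had medians of 0.26 and 0.24 with 11 of 21 members higher in both, but with siAkt1-22 the median (percentile 96.0) fell short of the upper limit set for random lists; without a filter (percentile 98.0) and with probe sets as the unit (percentile 99.8) it passed it. The plakoglobin gene JUP was 0.57 and 0.86, and E-cadherin, CDH1, 0.39 and 0.55. AKT and PI3K pathway members had medians of 0.01 (percentile 50.9) and 0.22 (percentile 99.1), with the mTOR partner RPTOR at 0.77 and 1.09 (0.15 and 0.15 in a dimmer probe set). The mTOR restraint TSC1 was 0.62 and 0.66 in its brightest probe set but -0.46 and 0.21 in another. FOXO targets, genes of the transcription factors that AKT phosphorylates, had medians of 0.44 with siAkt1-22 (percentile 99.9) and 0.10 with siAkt1-58 (percentile 92.4). Of the 25 measured, 8 were at least 2-fold higher and 2 at least 2-fold lower with siAkt1-22, and 1 (TXNIP) was at least 2-fold higher with both. Among p53 targets, with medians of 0.41 (percentile 99.8) and 0.05 (percentile 73.6), the growth factor GDF15 (2.36 and 1.55) and the CDK inhibitor CDKN1A (1.27 and 0.93) were higher, and the ubiquitin ligase MDM2 (-1.49 and -1.18) was lower. With probe sets as the unit, FOXO targets lay beyond the upper limit with both siRNAs (0.09 and 0.03), AKT and PI3K members with neither (0.01 and 0.02), and p53 targets above with siAkt1-22 (0.11) and below with siAkt1-58 (-0.01). Histone genes had medians of 0.09 and -0.03, with 5 of 10 measured members higher and 4 lower with both siRNAs. H2BC5 (1.93 and 1.03), H2BC21 (1.51 and 1.42) and H2AC6 (1.09 and 1.47) were at least 2-fold higher with both. H1-2 (-2.15 and -0.75) and H2AZ1 (-0.31 and -1.03) were lower.

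**Figure D3:**
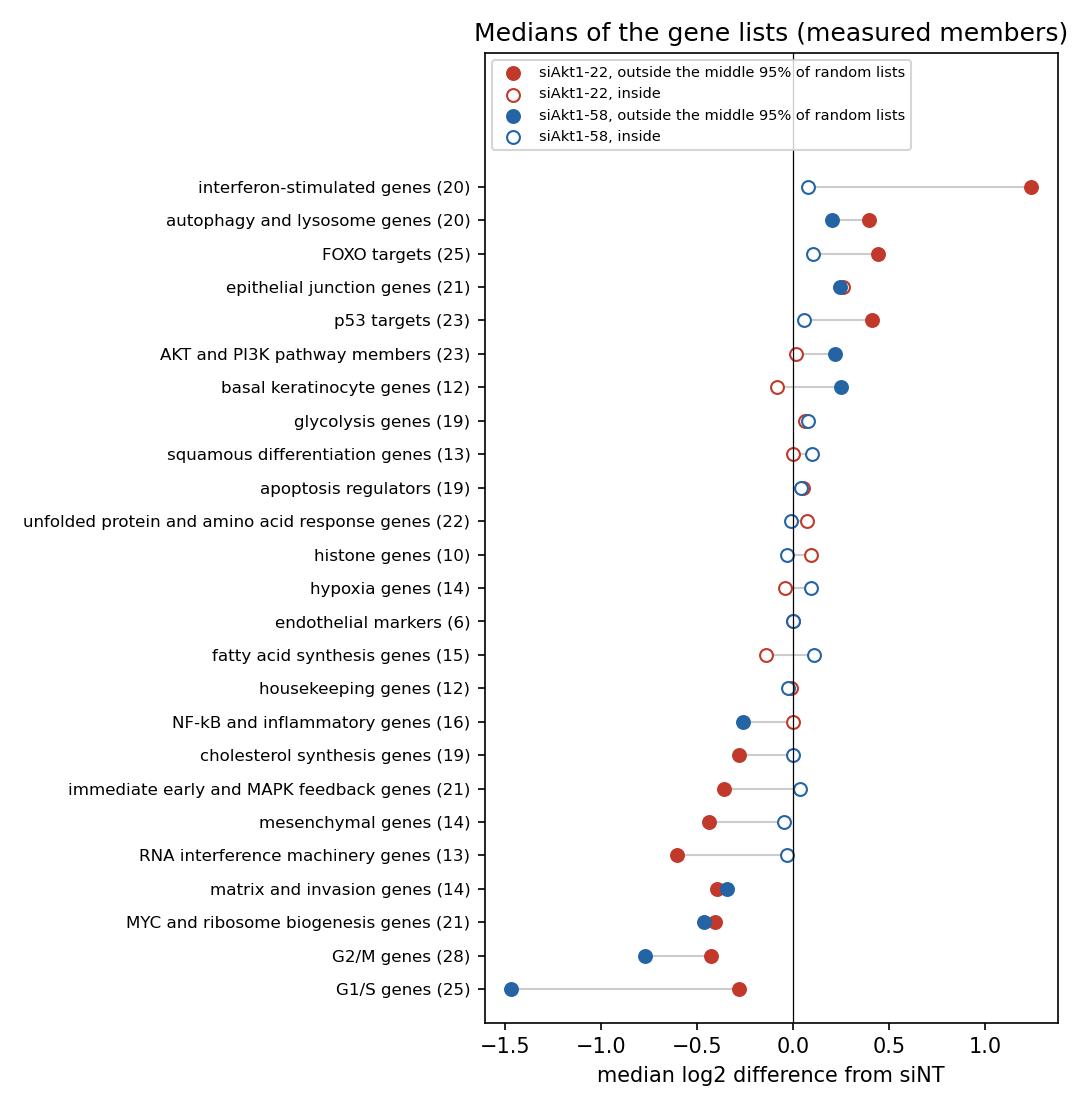
Median log2 difference from siNT (horizontal axis) of each of the 25 gene lists with at least 5 measured members, with the number of measured members in brackets; red marks siAkt1-22 and blue siAkt1-58, and filled points lie beyond the percentile limits set for random lists. The G1/S median is -1.47 with siAkt1-58, and the interferon-stimulated median is 1.24 with siAkt1-22.

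The siRNAs were also set against each other. GALNT1, which starts O-linked glycosylation, was 17.8-fold lower than siNT with siAkt1-22 and stood at 0.39 with siAkt1-58. PRKACA, the catalytic subunit of protein kinase A, was -3.49 and 0.43, the TGF-beta type II receptor TGFBR2 -2.65 and 1.11, the cytokine signalling inhibitor SOCS2 -2.31 and 1.63, and the integrin ITGB8 -1.51 and 2.58. In the opposite direction, the thymidylate synthase TYMS was 17.0-fold lower with siAkt1-58 and 0.37 with siAkt1-22. The mitochondrial mutase MMUT was 0.52 with siAkt1-22 and -3.73 with siAkt1-58, ARSB 0.53 and -2.70, ANO2 1.75 and -1.44, and the heme oxygenase HMOX1 3.34 and 0.17. In total there were 639 genes at least 2-fold higher with siAkt1-22 than with siAkt1-58 and 675 genes at least 2-fold lower with siAkt1-22 than with siAkt1-58, 1 library each and therefore without a test. A limit of 1.5-fold in place of 2-fold gave 1545 and 1381 in place of the 639 and 675.

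The median difference between the siRNAs within a gene was 1.05 for interferon-stimulated genes, the widest of the 25 lists. Their median against siNT was 1.24 with siAkt1-22 and 0.08 with siAkt1-58, and 13 of 20 were at least 2-fold higher with siAkt1-22 against 2 with siAkt1-58. The siAkt1-58 median lay at percentile 91.6, but beyond the limit without a filter (0.07, percentile 98.2) and with probe sets as the unit (0.12, percentile 99.3). The signalling factor IRF9 was 3.20 and 1.08, the RNA-sensing synthetase OAS1 1.68 and 1.52, and the RNA sensors RIGI 1.24 and 0.30 and IFIH1 1.24 and 0.48. Other probe sets gave 1.24 and 0.13 for IRF9 and 0.81 and 0.50 for OAS1. RNA interference machinery genes had medians of -0.61 (percentile 0.2) and -0.03 (percentile 19.4). The small RNA processing enzyme DICER1 was -2.43 and -0.16, and AGO2, the slicing Argonaute, -0.84 and -0.19, while the silencing scaffold TNRC6B was 0.83 and 0.90 and AGO4 0.56 and 0.26. With probe sets as the unit the RNA interference list was at -0.06 with siAkt1-22 (percentile 3.21), no longer beyond the limit. In the same siAkt1-22 library the actin gene ACTB was -3.09 with siAkt1-22 and 0.21 with siAkt1-58, while GAPDH was -0.05 and 0.02, and the spiked poly-A control probe sets had medians of -0.56 and -0.01. The difference between the siRNAs was not tested for any list.

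**Figure D4:**
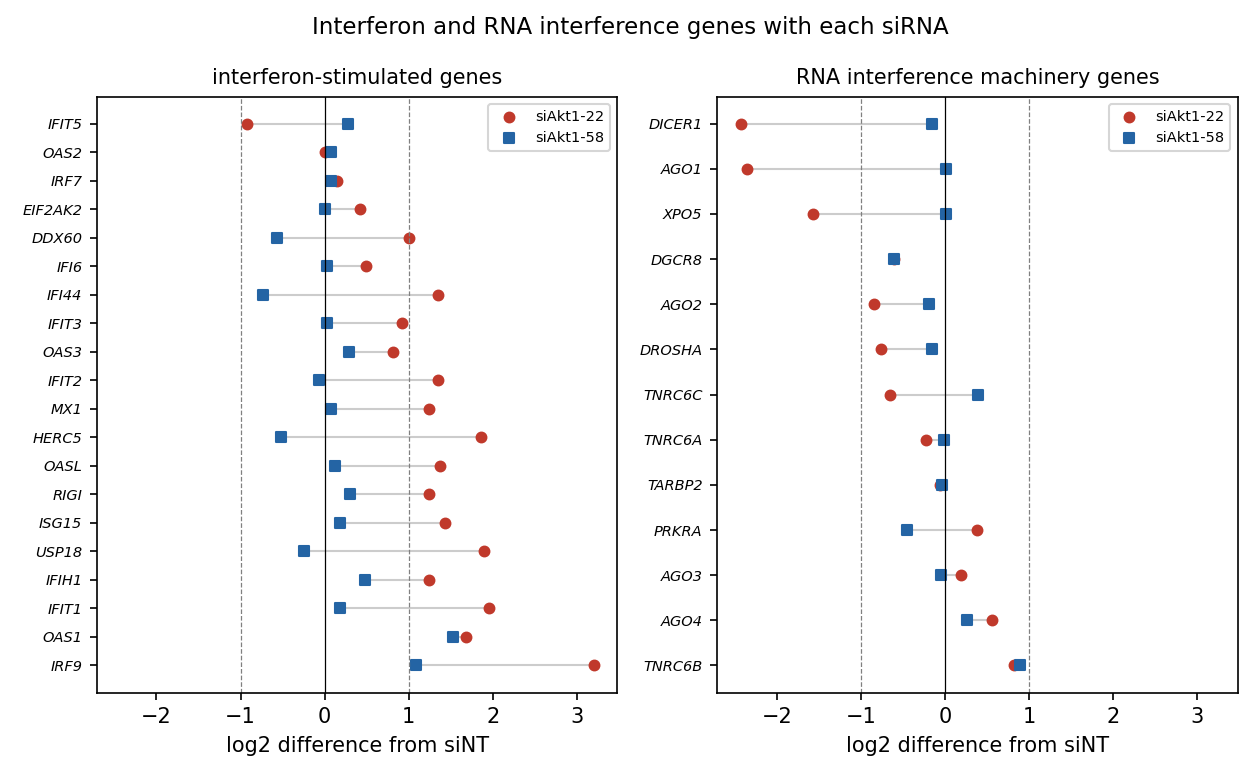
Log2 difference from siNT (horizontal axis) of each measured interferon-stimulated gene (left) and RNA interference machinery gene (right), with siAkt1-22 as red circles and siAkt1-58 as blue squares; dashed lines mark 2-fold. IRF9 lies at 3.20 and DICER1 at -2.43 with siAkt1-22.

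The count of genes in which 1 library stood at least 2-fold from both others on one side was 244 for siNT, 680 for siAkt1-22 and 256 for siAkt1-58. With 3 libraries there are 3 such partitions, and siNT was not the library that stood apart most. Averaged probe sets gave 142 genes with siNT at least 2-fold from both other libraries on one side and 161 genes with siAkt1-58 at least 2-fold from both other libraries on one side.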

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

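The tests of explanations in this part (the rank of AKT1, the use of the library counts as a test of chance, the loess correction, the ACTB control probe sets, the immune cell markers and the interferon ligands) were chosen after the results they bear on had been seen, with limits set knowing the values; the simulation and the counts themselves were planned.

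Some probe sets that the comparisons by gene leave out also met the size rule. Among the 2713 probe sets without a listed gene, 4 were at least 2-fold higher and 16 at least 2-fold lower than siNT with both siRNAs. Among the 1327 probe sets with several genes, 7 were higher and 5 lower by the same rule. Genes in simulated unchanged libraries met this rule too, so these counts do not show an effect. The 24 poly-A control probe sets, which read RNA spiked in before labelling, had a median of -0.564 with siAkt1-22 (from -1.25 to -0.35) against -0.013 with siAkt1-58, while the hybridisation controls, added after labelling, had a median of -0.041 with siAkt1-22.

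The siNT library stood apart from both siAkt1 libraries in 244 genes, close to the 256 for siAkt1-58 and below the 680 for siAkt1-22. A chance deviation of the lone siNT library would put no particular gene first, yet AKT1, named by the design, ranked 1 of 12779 genes, which argues against chance for AKT1. For the other genes chance and an effect of AKT1 knockdown cannot be told apart, because 1 control library enters every difference. Shared shifts of cell cycle and ribosome biogenesis genes may reflect AKT1 loss, or a siNT culture that happened to grow faster. Nothing in these 3 libraries separates these readings. The G1/S median was -0.28 with siAkt1-22 and -1.47 with siAkt1-58, although AKT1 read -3.08 and -3.28. Neither reading by itself accounts for that gap between the siRNAs, and its cause was not tested.

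The siAkt1-22 library stood apart from both others in 680 genes and, after a loess correction for the trend with intensity, in 673. The fitted curve moved no gene of this library by more than 0.0561, so a smooth trend with intensity in the deposited values does not account for these genes. RMA had already equalised the distributions of the arrays. Labelling or normalization differences that leave no such trend could not be tested this way and stay open beside the poly-A controls at -0.564. ACTB was part of this pattern, and its 3' control probe set was -3.21 with siAkt1-22 (the 5' one -4.04). RNA degradation from the 5' end would have spared the 3' probe set, and the 5' GAPDH control was -0.08, so degradation does not account for ACTB. Pairing of siAkt1-22 with other mRNAs may contribute and was not tested, since the siRNA sequences are not given in the sources used here.

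Interferon-stimulated genes were higher with siAkt1-22 (median 1.24), and the median was 1.23 after the same loess correction. A smooth trend with intensity in the deposited values thus does not account for them. Labelling or normalization differences that leave no such trend could not be tested this way and stay open. Immune cells in the culture stay open by these tables: the median difference of the 12 immune cell markers with a named probe set was 0, but only 4 of them lay above the filter level, and PTPRC and LYZ read 2.89 and 3.14 in every library. Interferon made by the cells stays open too, since the highest difference among the interferon ligand genes was 0.24, for IFNB1, which lay near the floor at 3.15 with siNT. An effect of AKT1 knockdown was not tested apart from these; with siAkt1-58 the median was 0.08, beyond the limit for random lists without a filter and with probe sets as the unit but not as reported.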

How the results depend on the processing

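The loess correction and the removal of tied genes were chosen after seeing the data; they gave 96 and 94 genes at least 2-fold higher than siNT in both siAkt1 libraries and 146 and 149 genes at least 2-fold lower than siNT in both siAkt1 libraries, against 94 and 150. Averaging the probe sets of a gene gave 43 and 99, of which 38 and 88 were shared; AKT1 at -1.48, because its dim probe sets enter the mean; 142 genes with siNT at least 2-fold from both other libraries on one side and 161 genes with siAkt1-58 at least 2-fold from both other libraries on one side; and 6 lists past camera. There were 639 genes at least 2-fold higher with siAkt1-22 than with siAkt1-58, 675 genes at least 2-fold lower with siAkt1-22 than with siAkt1-58, and 680 genes with siAkt1-22 at least 2-fold from both other libraries on one side. With a 1.5-fold limit in place of 2-fold, the shared genes numbered 409 and 458, those between the siRNAs 1545 and 1381, and those with siNT, siAkt1-22 or siAkt1-58 apart 867, 1731 and 806. Median centring gave 6 lists past camera. An estimated correlation gave 0, but with 1 residual degree of freedom that setting could hardly pass any list. Lists called higher numbered 1 as reported, 3 without a filter, 0 with the stricter filter and 4 with probe sets as the unit; the cause was not tested. Leaving out 1 siAkt1 library gave 197 to 562 higher and 457 to 763 lower genes, 4 higher lists either way and 5 to 8 lower lists. The higher lists were mostly different ones, with only autophagy and lysosome genes higher either way. Limma called 0 genes under each of its alternatives, with 954 at an unadjusted p under 0.05 as reported; in a design this small that says nothing about stability. The other 78 values that answer a comparison stayed within their limits. For 166 named genes and 25 lists 952 values did so, 103 moved and 0 called ones changed sign; there, leaving out a library cannot move a mean by 1 SD, so it tests nothing. No paired analysis was possible because siNT has 1 library and the groups share 1 replicate number.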

Other observations

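The lists in the last paragraph were chosen after seeing the data. Among the remaining lists, several stood apart with siAkt1-22 and not with siAkt1-58. Mesenchymal genes had medians of -0.44 and -0.05, with the matrix protein SPARC at -2.28 and -0.47 (-2.26 and 0.22 in another probe set) and the transcription factor SNAI2 at -0.82 and -0.60; without a filter on dim genes the medians were 0 and 0, inside the limits, and with probe sets as the unit -0.47 and -0.10, beyond the limit with both. Cholesterol synthesis genes had medians of -0.28 and 0, with INSIG1, a brake on sterol synthesis, at -0.88 and -0.66. Immediate early and MAPK feedback genes had medians of -0.36 and 0.04, with HBEGF at -0.90 and -0.51 and JUN at -0.66 and -1.01. NF-kB and inflammatory genes had medians of 0 and -0.26, beyond the limit with siAkt1-58 alone. The chemokine CXCL1 was -0.35 and -1.79 (0 and -0.18 in another probe set), whereas the interleukin gene IL1B was lower with siAkt1-22 (-2.47) than with siAkt1-58 (-0.93). Basal keratinocyte genes had medians of -0.09 (percentile 11.2) and 0.25 (percentile 98.75), likewise beyond the limit with siAkt1-58 alone. With probe sets as the unit, NF-kB genes were also beyond the upper limit with siAkt1-22 (0.16) and basal genes beyond the lower one (-0.08). The difference between the siRNAs was not tested for these lists.

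Fatty acid synthesis genes (-0.14 and 0.11), glycolysis genes (0.06 and 0.08), hypoxia genes (-0.04 and 0.09), apoptosis regulators (0.05 and 0.04), unfolded protein and amino acid response genes (0.07 and -0.01), squamous differentiation genes (0 and 0.10), housekeeping genes (-0.01 and -0.03) and endothelial markers (0 and 0) had medians inside the chosen percentiles with both siRNAs. With probe sets as the unit, hypoxia genes lay beyond the lower limit with siAkt1-22 (-0.17) and the upper one with siAkt1-58 (0.14), and fatty acid synthesis genes beyond the lower one with siAkt1-22 (-0.23). Of fibroblast markers 3 and of immune cell markers 4 were measured, with medians of 0 and 0 and of 0.06 and 0.06, too few for a percentile.

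TGF-beta signalling genes had medians of -0.15 and 0.16 and included TGFBR1, CDKN2B, the inhibitors of differentiation ID1 (0.76 and 1.15) and ID2 (3.22 and 1.31), and SKIL (-0.73 and -1.37). SRF and actin cytoskeleton genes had medians of 0.06 and -0.02 although ACTG1 was -2.61 and -0.11 and the myosin heavy chain MYH9 -1.81 and -0.45. Interferon ligands and sensors had medians of 0.53 and 0.23. With siAkt1-22, AGO1 (-2.35) and XPO5 (-1.57) were lower beside DICER1, against 0.02 and 0.01 with siAkt1-58, and CCND2 was -5.02 against -1.30; these were picked for their values.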
